A study of Mus musculus with 7 samples.

How the data were processed

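Total RNA from mouse ileum and colon was extracted with an RNeasy kit and labelled with biotin by the Affymetrix sense target kit, per the labels' protocols, and 1 array was run per sample. Samples were grouped by tissue, genotype and treatment as the labels give them, which makes 6 groups, with 2 arrays for KO colon after DSS and 1 for each of the others. The authors deposited one intensity per probe set and array. How the authors summarised and normalized these values is not given in the sources used here. The deposited values are linear, run from 10.4 to 22236.4 and have array medians within a narrow range, so they were taken as already normalized between arrays, and log2 of each value was computed here. The test had been planned for deposited log2 values and was run on these computed log2 values. A summary to probe sets hides disagreement within a probe set, and if an unstated step equalised arrays, a shift shared by all genes would be lost.

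The table holds 35512 probe sets. The platform annotation names 1 gene symbol for 21789 of them, several for 1621 and none here for 12102, and only those with 1 symbol were named. Where a gene had several probe sets (999 genes), the one with the highest mean over all arrays was used, which left 19938 genes. Chromosomes came from the RefSeq annotation of GRCm38.p6, used only for chromosome membership; 99.9% of the genes tested had one. No build is given for the array, so no coordinates are printed.

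Models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A first model held the condition (control ileum, control colon, DSS colon) and the genotype, with 3 residual degrees of freedom, and gave the genotype, DSS and tissue comparisons. Its error is therefore the disagreement of the KO effect between conditions together with the spread of the KO DSS pair. A second model with 5 coefficients let the genotype effect differ between controls and DSS colon, with 2 residual degrees of freedom, and gave the KO against WT comparison in DSS colon and the interaction. Values printed with ± are log2 differences with the standard error of the fit. Comparisons of 1 array with 1 array are given as values without a test.

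Before the data were examined, 38 gene lists were fixed from textbook knowledge of intestinal cell types, colitis, autophagy and possible admixed tissue; 37 were tested, and 590 of their 654 genes were measured. List tests used camera with a preset correlation of 0.01, camera with an estimated correlation and fry, adjusted over the 37 lists in each comparison. With the preset value camera called 17 lists for DSS, 13 for tissue, 17 for genotype, 15 for KO against WT in DSS colon and 17 for the interaction. With an estimated correlation it called 0 in each. The rule for named genes was also fixed then. It takes the 10 largest changes each way among genes past the threshold that moved the same way in every condition or array pair and whose mean, in the group where they are higher, lay above the median of all gene values (7.33), leaving out predicted genes, small RNAs, receptor segments and sex markers. Where fewer than 5 passed, it fills up to 5 with genes that did not pass. It adds members from among the 4 with the largest change in each list described, and for the interaction and single pairs takes 5 each way. Single-pair medians of lists were set against 10000 random lists matched on mean expression.

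The scripts were tested on simulated data with 200 changed genes per comparison. At a change of 1 log2 unit they recovered 76.4% of the genes for genotype, 69.9% for DSS and 51.6% for tissue, and at 0.6 they recovered 14.0%, 4.84% and 0%. The Benjamini-Hochberg cut-off is looser when many genes differ. In the measured genotype comparison 1 gene passed, so the simulated shares may overstate what could be recovered there. Alternatives were quantile normalization, centring each array, leaving out dim genes, testing all probe sets, averaging probe sets, a variance trend with robust fit, labelled sex as a covariate, a 6-group model, colon arrays alone, and leaving out each array. Labelled sex could not be separated from the interaction. The sex markers went against that label in 3 arrays, so the covariate does not adjust for the sex that the markers show. Figures were drawn with matplotlib 3.10.9.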

Results

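RNA from the intestine of wild-type (WT) mice and of mice lacking Atg4b was hybridised to 7 one-colour Affymetrix arrays, 3 from WT and 4 from knockout (KO) animals on a mixed C57Bl6/129Sv background, all 3 months old. Atg4b encodes a cysteine protease that trims the LC3 and GABARAP proteins needed to build autophagosomes. Ileum and colon of untreated mice gave 1 array per genotype and tissue. Colon of mice given dextran sulfate sodium (DSS), a compound in drinking water that injures the colonic epithelium and causes colitis, for 7 days followed by 3 days of water gave 2 KO arrays and 1 WT array. The series asked how loss of Atg4b alters the intestinal transcriptome during this chemically induced colitis. The median probe-set intensity lay between 121.4 and 126.45 on the 7 arrays, and 19938 genes were tested. The number of arrays limits the precision, and 5 of the 6 groups held a single array. The labels do not say whether each array is a separate animal, so p-values measure only the spread between these arrays.

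Atg4b itself separated the genotypes in every array. Its log2 intensity was 7.35 to 7.72 in the 3 WT arrays and 5.39 to 5.45 in the 4 KO arrays, below the lower quartile of all genes on those KO arrays. Markers of sex did not follow the labels. Xist, the noncoding RNA expressed from the inactive X chromosome of females, was at 5.19 to 5.52 in the 4 control arrays and at 12.16 to 12.55 in the 3 DSS arrays. The Y-linked Eif2s3y showed the opposite, with 9.39 to 9.77 in control arrays and 4.28 to 4.39 in DSS arrays, and Kdm5d and Uty went the same way as Eif2s3y. The markers went against the labelled sex in 3 arrays, all of them WT, and matched it in the other 4. Every DSS array therefore had the female pattern and every control array the male one, so that DSS and measured sex cannot be told apart in any gene, whereas WT and KO arrays of the same condition shared their sex pattern.

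**Figure D1:**
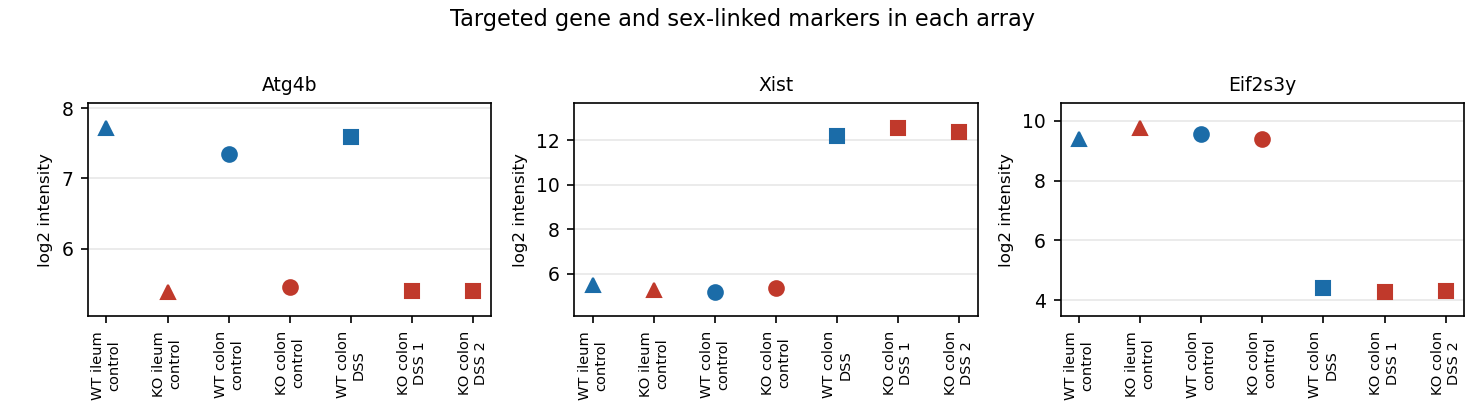
Log2 intensity (vertical axis) of Atg4b, Xist and Eif2s3y in each of the 7 arrays (horizontal axis), with WT in blue, KO in red, triangles for ileum, circles for control colon and squares for DSS colon; each point is 1 array. Atg4b lies between 5.39 and 5.45 in the KO arrays, and Xist is above 12 only in the 3 DSS arrays.

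In DSS-treated colon, genes of interferon signalling, inflammatory cytokines and antimicrobial defence rose, while several cytochromes P450 fell. Ido1, the interferon-induced enzyme that degrades tryptophan, rose by 6.01 ± 0.33 log2 units (SE, 3 DSS against 2 control arrays). Its control values of 5.67 in WT and 5.94 in KO lay near the lower quartiles of all genes on these arrays (5.77 and 5.87), where a fold may be understated. All 3 DSS arrays had the female and both control colons the male pattern of Xist and Eif2s3y. Nos2, the inducible nitric oxide synthase, rose by 5.46 ± 0.37, the T cell chemokine Cxcl9 by 5.09 ± 0.23 and the interferon-induced GTPase Iigp1 by 4.83 ± 0.10. The acute-phase gene Saa3 (4.77 ± 0.20), the cytokines Il1b (4.73 ± 0.17) and Il1a (4.65 ± 0.51), Clca4b (4.71 ± 0.51) and Acod1, the enzyme that makes itaconate in activated macrophages (4.45 ± 0.24), followed. The antimicrobial lectin Reg3g rose by 4.84 ± 1.17, just past the threshold (adjusted p = 0.0499), with 7.69 in KO replicate 1 against 3.89 in KO replicate 2 and 3.33 in WT, and it passed without KO replicate 1 (3.61) but not without any other single array (4.21 to 5.94). On the lower side were the pentraxin Mptx1 (-4.86 ± 0.47), the cytochromes P450 Cyp2c68 (-3.59 ± 0.45), Cyp2f2 (-3.41 ± 0.19) and Cyp2d12 (-3.32 ± 0.26), Slc37a2 (-3.35 ± 0.36), transthyretin Ttr (-3.02 ± 0.13), the matrix proteoglycan Ogn (-2.97 ± 0.38), Nxpe2 (-2.95 ± 0.50), the elastase Cela1 (-2.55 ± 0.12) and endothelin Edn1 (-2.53 ± 0.33). In limma, 1436 genes were higher and 684 lower in DSS colon at an adjusted p under 0.05, and 453 and 262 of them differed by more than 2-fold. The DSS difference in WT colon and that in KO colon, which share no array, correlated across genes with r = 0.76. Genes are not independent replicates. Of these 20 genes 11 passed without the WT control colon and 12 without the KO control colon, all in the same direction, which the naming rule had already required of every array pair. Il1a and Reg3g, with control values from 4.75 to 5.06, lay below the lower quartile on both control arrays, so their rises may be understated as well. Cyp2d12 lay below it on 1 of the 3 DSS arrays.

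**Figure D2:**
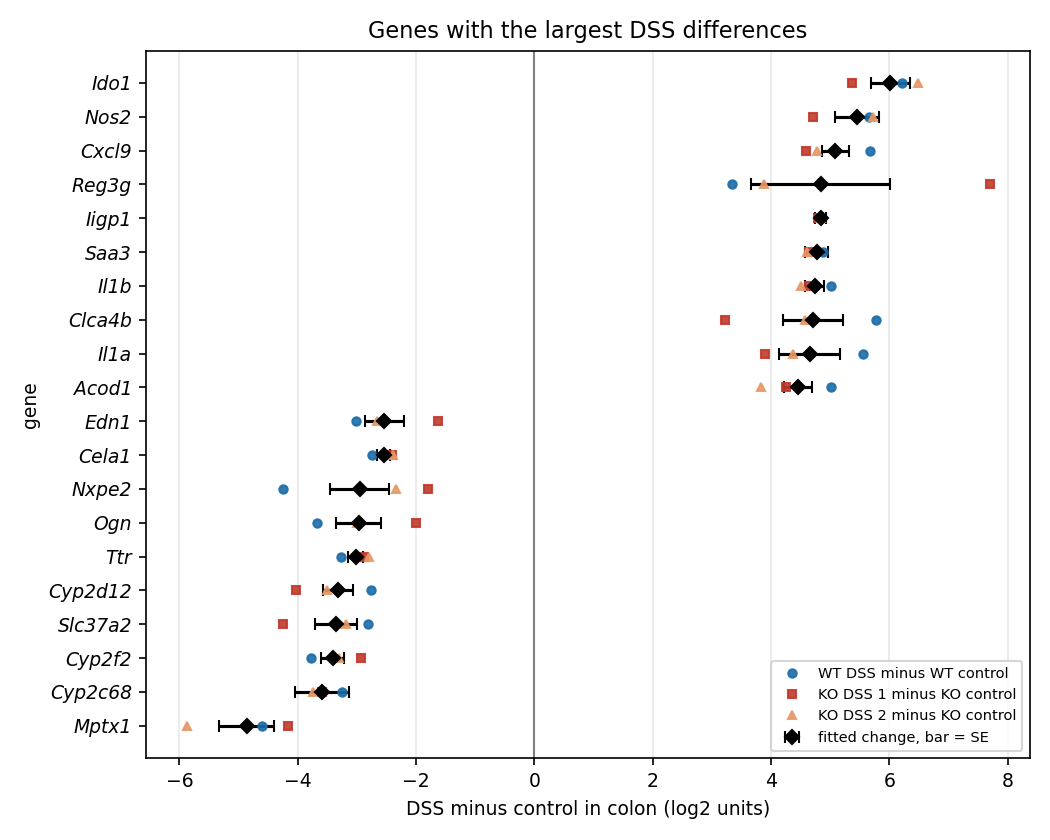
Change in log2 units between DSS and control colon (horizontal axis) for the 20 named genes (vertical axis); black diamonds are the fitted changes with SE, and coloured points are single DSS arrays minus the control colon array of their own genotype. Ido1 is at 6.01 and Mptx1 at -4.86, and Reg3g has the widest spread, from 3.33 to 7.69.

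Among gene lists fixed in advance, the interferon response rose as a whole. All 21 measured members rose, over all genes and adjusted over the list alone, by a median of 2.71, led by Iigp1, Ifit2 (3.77 ± 0.15), Usp18 (3.25 ± 0.18) and Oas2 (3.11 ± 0.16). The adjusted p of this list was 2.60e-25 in camera and 0.186 with an estimated correlation. Of the cytokine and chemokine list 19 of 28 members rose (21 adjusted over the list alone), among them Cxcl9, Il1b, Il1a and Ccl3, the last by 4.41 ± 0.40 (adjusted p = 0.406 with an estimated correlation). Of the neutrophil list 12 of 19 rose (15 adjusted over the list alone), including Clec4e (3.28 ± 0.40) and the calprotectin subunits S100a9 (2.61 ± 0.28) and S100a8 (2.28 ± 0.18), with an adjusted p of 0.430 with an estimated correlation. Of the macrophage list 8 of 18 were higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p = 0.510 with an estimated correlation), with Tyrobp at 1.43 ± 0.24 and Ccr2 at 1.01 ± 0.14. Antigen presentation by MHC class II rose in 6 of 8 members, over all genes and adjusted over the list alone, with H2-DMa at 1.41 ± 0.21 and Cd74 at 1.02 ± 0.22 (adjusted p = 0.510 with an estimated correlation). Matrix-degrading and wound genes rose in 6 of 13 members (7 adjusted over the list alone), with the collagenase Mmp13 at 3.44 ± 0.23, the stromelysins Mmp10 and Mmp3 at 2.48 ± 0.28 and 2.47 ± 0.26 and their inhibitor Timp1 at 2.07 ± 0.19 (adjusted p = 0.430 with an estimated correlation). In the epithelial antimicrobial list 9 of 20 members were higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p = 0.474 with an estimated correlation), with Nos2, Reg3g and Saa3 in the lead and Reg3b at 4.48 ± 1.23, which did not pass. Complement genes rose in 4 of 10 members (7 adjusted over the list alone), with C2 at 1.39 ± 0.26 and C4b at 1.19 ± 0.16 (adjusted p = 0.509 with an estimated correlation).

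Proliferation and protein-folding genes moved upwards too. In the cell cycle list 12 of 24 members rose (16 adjusted over the list alone) by a list median of 0.77, with Rrm2 at 1.70 ± 0.25 and the replication licensing factor Mcm3 at 1.40 ± 0.23 (adjusted p = 0.510 with an estimated correlation). In the endoplasmic reticulum stress list 12 of 20 rose (14 adjusted over the list alone), with Asns at 1.65 ± 0.16, Creld2 at 1.53 ± 0.19 and Hyou1 at 1.22 ± 0.17 (adjusted p = 0.509 with an estimated correlation). Of 14 goblet cell genes 2 were lower, Clca1 (-0.98 ± 0.21) and Creb3l1 (-0.77 ± 0.11), while Retnlb stood at 3.36 ± 0.88 and did not pass. The median of that list was -0.13 and its mean 0.05, with 1 higher and 2 lower adjusted over the list alone, and camera did not call it except without the KO control colon (median -0.30, adjusted p = 0.0300) and, with the other sign, with smooth muscle markers as a covariate (0.46, adjusted p = 0.00866). Colonocyte markers went both ways and camera did not call them, with 4 of 19 higher, such as Clca4a (1.57 ± 0.20), and 4 lower, such as the sulfate transporter Slc26a2 (-1.21 ± 0.17), the same counts as adjusted over the list alone. Of 15 crypt stem cell genes 2 were lower, Axin2 among them (-0.73 ± 0.13), while Lgr5 stood at -1.31 ± 0.53 and did not pass, with 7 lower and 1 higher adjusted over the list alone (list median -0.60, and -0.35 without the WT control colon; adjusted p = 0.510 with an estimated correlation). In the colon regional identity list 6 of 14 genes fell and 1 rose (7 and 1 adjusted over the list alone), with Hoxd10 at -2.35 ± 0.31 and Hoxd11 at -1.71 ± 0.26 (adjusted p = 0.406 with an estimated correlation). In the xenobiotic metabolism list 5 of 19 fell (8 adjusted over the list alone), with the efflux pump Abcb1a at -2.44 ± 0.46 and Gstm1 at -1.55 ± 0.27 (adjusted p = 0.509 with an estimated correlation). The mean of that list was 8.40 in WT and 8.30 in KO control colon. It was 7.25 in WT DSS colon and 7.29 in KO DSS replicate 2, but 8.12 in KO DSS replicate 1, where the fall was small. Fry, which tests whether the genes of a list move, on balance, one way, and does not compare them with other genes, called 9 lists. These were interferon (adjusted p = 0.00212), cytokines and chemokines, neutrophil, antimicrobial, tissue remodelling, endoplasmic reticulum stress, colon regional identity, oxidative response and pancreas acinar.

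Markers of the muscle layer moved with DSS beside these groups. All 14 smooth muscle genes had negative values with a median of -1.55 (-0.97 without the WT DSS array), and 3 passed, Des among them at -1.97 ± 0.43 (12 adjusted over the list alone; adjusted p = 0.510 with an estimated correlation). The mean log2 intensity of this list was 11.02 in WT and 10.97 in KO control colon but 10.55 in KO DSS replicate 1, 9.58 in KO DSS replicate 2 and 9.03 in WT DSS colon. With that mean as a covariate, added after seeing the data, 313 genes passed, 251 of them shared with the 2120 above. The list medians were then 2.11 for interferon, 1.13 for cytokines and 1.07 for neutrophils, all still called by camera. Those of MHC class II (0.46, adjusted p = 0.0826), macrophages (0.34, adjusted p = 0.0827), complement (0.34, adjusted p = 0.0697), cell cycle (0.26, adjusted p = 0.0697) and crypt stem cells (-0.25, adjusted p = 0.144) were no longer called. The smooth muscle mean was lower in every DSS array than in either control colon, so the covariate takes up part of the DSS difference itself. Lost calls or changed signs with it therefore do not show that muscle accounts for a list. Adipocyte genes, 1 of 11 lower over all genes and adjusted over the list alone (Pck1, -1.92 ± 0.45), had a median of -0.52 (adjusted p = 0.0430 in camera and 0.891 with an estimated correlation), which became 0.73 with the covariate. It became 0.29 without the WT control colon and -1.32 without the KO control colon. The list was not called without the WT DSS array (-0.04, adjusted p = 0.595), without KO DSS replicate 2 (adjusted p = 0.0550) or without either ileum array (adjusted p = 0.0519). The count of genes depended on single arrays. It was 216 without the WT control colon, 183 without the KO control colon, 800 without KO DSS replicate 2, 526 without the WT DSS array and 3549 without KO DSS replicate 1. Under quantile normalization the split was 1267 higher and 983 lower.

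**Figure D3:**
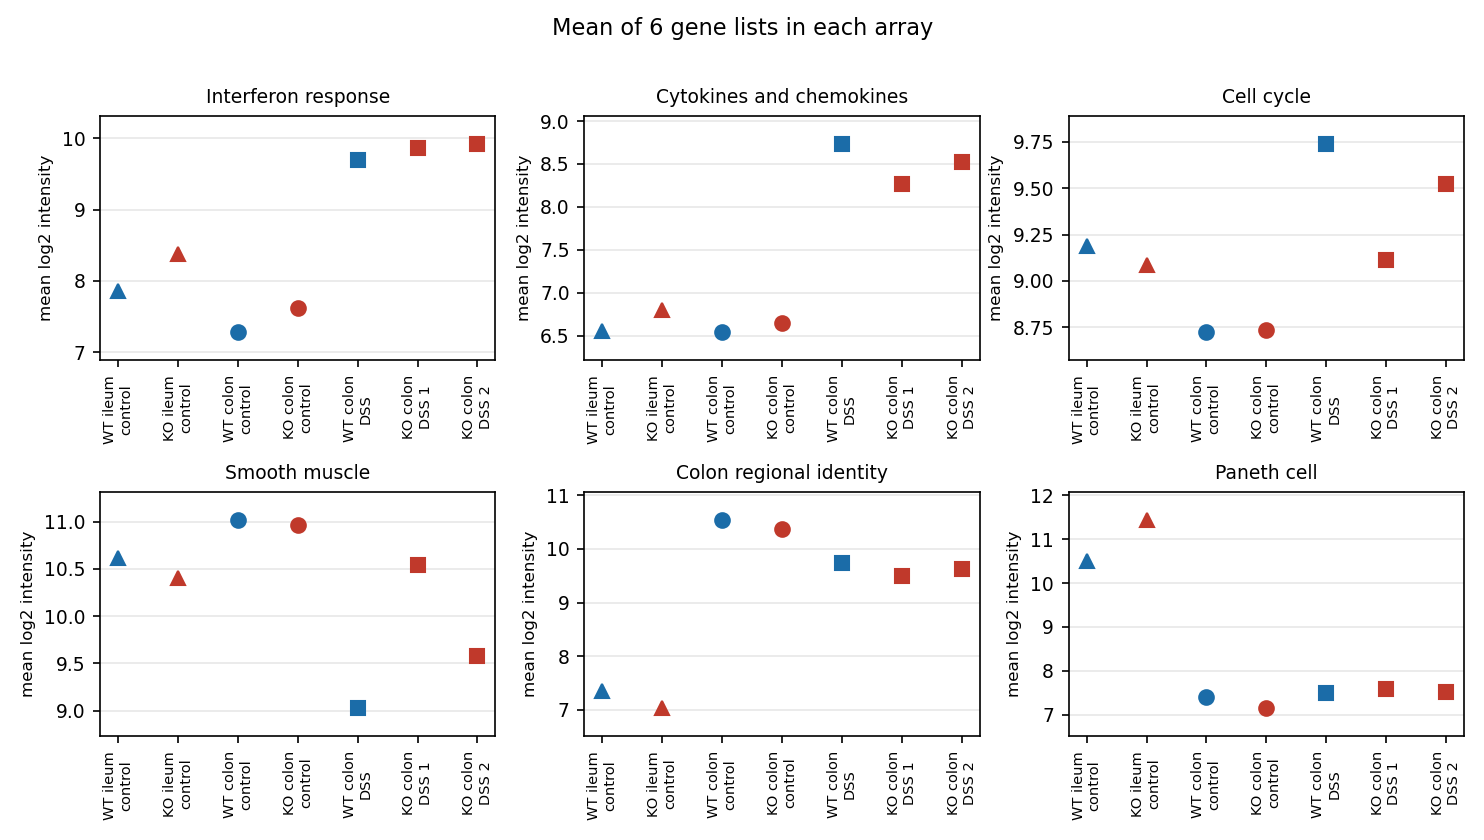
Mean log2 intensity (vertical axis) of 6 fixed gene lists in each of the 7 arrays (horizontal axis), with colours and symbols for genotype and condition as in the plot of Atg4b. The interferon list lies at 7.28 and 7.62 in control colon and between 9.69 and 9.92 in DSS colon, and the smooth muscle list is lowest in WT DSS colon at 9.03.

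The control arrays show how ileum and colon differ (2 against 2 arrays). The alpha-defensin Defa24 was higher by 8.70 ± 0.26 log2 units, sucrase-isomaltase Sis by 8.23 ± 0.14, the ileal bile acid binding protein Fabp6 by 7.34 ± 0.16, the sulfate transporter Slc13a1 by 7.17 ± 0.58, the vitamin B12 receptor subunit Cubn by 6.85 ± 0.13 and apolipoprotein Apoa1 by 6.54 ± 0.13. Reg3g and Reg3b were higher by 8.39 ± 1.27 and 7.94 ± 1.33, Malrd1 by 6.66 ± 0.31 and Defa39 by 6.42 ± 0.34. In colon the water channel Aqp8 (-5.98 ± 0.18 for ileum minus colon), the carbonic anhydrases Car1 (-5.78 ± 0.58) and Car2 (-5.76 ± 0.25), the transglutaminase Tgm3 (-6.97 ± 0.58) and Sycn (-5.65 ± 0.20) were higher. So were the posterior homeobox gene Hoxb13 (-5.63 ± 0.58), Nxpe2 (-5.62 ± 0.55), Sval1 (-5.36 ± 0.28), B3galt5 (-5.30 ± 0.12) and Ly6g (-7.46 ± 0.15). For 11 of these 20 genes, Defa24, Reg3g, Sis, Reg3b, Fabp6, Slc13a1, Cubn, Malrd1, Defa39, Ly6g and Hoxb13, the values in the tissue where they are lower lay below the lower quartile on both arrays. Those differences may be understated, and the order among them is not settled. In limma 1184 genes were higher and 642 lower in ileum at an adjusted p under 0.05, 609 and 336 of them by more than 2-fold.

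Of the small intestinal absorptive list 22 of 24 genes were higher in ileum, over all genes and adjusted over the list alone, with a median of 3.89 (adjusted p = 7.86e-30 in camera and 0.157 with an estimated correlation). Of 9 Paneth cell genes 6 were higher (7 higher and 1 lower adjusted over the list alone), with Lyz1 at 5.90 ± 0.11 and Itln1 at 5.53 ± 0.21 (adjusted p = 0.531 with an estimated correlation). The colon regional identity list was lower in 13 of 14 members (14 adjusted over the list alone), with a median of -3.03 (adjusted p = 0.0945 with an estimated correlation). In the epithelial antimicrobial list 4 of 20 genes were higher and 2 lower (7 and 4 adjusted over the list alone), and camera did not call it except without the KO ileum (median 0.29, adjusted p = 0.0237). Of 18 T and NK cell genes 6 were higher (13 adjusted over the list alone), with Gzmb at 2.85 ± 0.17 and Cd3g at 2.55 ± 0.35 (adjusted p = 0.531 with an estimated correlation). In the MHC class II list 6 of 8 were higher and 1 lower, the same adjusted over the list alone, with H2-DMa at 2.31 ± 0.23 (adjusted p = 0.820 with an estimated correlation). Of 17 B and plasma cell genes 4 were higher and 1 lower (4 and 3 adjusted over the list alone), with a median of -0.31, and camera did not call them except without the WT control colon (-0.68, adjusted p = 0.0292). In the interferon list 7 of 21 were higher (13 adjusted over the list alone), with Ifit1 at 1.89 ± 0.29 (adjusted p = 0.370 with an estimated correlation). Among the hormones of enteroendocrine cells, Insl5 was lower in ileum (-4.68 ± 0.46) while neurotensin Nts (4.17 ± 0.16) and secretin Sct (1.40 ± 0.18) were higher; of that list 4 of 16 were higher and 3 lower (4 and 5 adjusted over the list alone), and camera did not call it. Adipocyte markers were also higher in ileum, 3 of 11 members (7 higher and 1 lower adjusted over the list alone), with Adipoq at 2.49 ± 0.49 (adjusted p = 0.820 with an estimated correlation), and camera did not call them without the KO control colon (median 0.60, adjusted p = 0.101). Fry called 8 lists, the absorptive, Paneth, regional, T and NK cell and interferon lists among them. The count of genes fell to 1003 without the WT ileum, 709 without the KO ileum, 812 without the WT control colon and 660 without the KO control colon.

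For the effect of the knockout across ileum, control colon and DSS colon (4 KO against 3 WT arrays), Atg4b alone passed in limma. The KO minus WT difference of Atg4b was -2.15 ± 0.10 log2 units (adjusted p = 0.00727), with -2.33 in ileum, -1.90 in control colon and -2.19 in DSS colon. At an unadjusted p under 0.05 there were 720 of the 19938 genes, Atg4b included. That is fewer than this threshold would pass on average if no gene differed. Of the 35 autophagy genes on the fixed list none passed, over all genes or adjusted over the list alone, and the widest difference was -0.22 ± 0.12 for the LC3 gene Map1lc3a. None of the 12 genes next to Atg4b on its chromosome passed either way, the widest being Thap4 at -0.25 ± 0.11. Among the genes that the naming rule ranks, the largest values that kept their direction in all 3 conditions were those of the interferon-induced Ifi44l (1.89 ± 0.64), Pm20d1 (1.38 ± 0.35), the Wnt antagonist Sfrp1 (1.23 ± 0.33), dermatopontin Dpt (0.99 ± 0.29) and Plb1 (0.96 ± 0.27) on the higher side. On the lower side they were those of tyrosine aminotransferase Tat (-1.21 ± 0.40), Saa1 (-1.20 ± 0.60), Mptx1 (-1.08 ± 0.39) and the iron exporter Slc40a1 (-0.95 ± 0.42), all of them with an adjusted p of 0.989. Sizes differed between ileum, control colon and DSS colon in that order. Ifi44l was at 1.22, 0.19 and 3.67, Tat at -2.55, -0.90 and -0.44, Saa1 at -3.43, -0.09 and -0.35 and Slc40a1 at -2.50, -0.54 and -0.10. Mptx1 was more even (-0.80, -0.96 and -1.37). Since Pm20d1 did not pass at 1.38 ± 0.35, the single call does not argue against KO changes of 1 log2 unit, whatever share the simulation recovered.

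Some lists leaned one way without a single member passing over all genes. In the interferon list 20 of 21 values were above 0 in KO arrays with a median of 0.34, and 8 passed adjusted over the list alone, with Ifit1 at 0.81 ± 0.23, Ifit3 at 0.73 ± 0.15 and Oasl2 at 0.71 ± 0.12. The list median was 0.58 in ileum, 0.33 in control colon and 0.18 in DSS colon. In the fibroblast matrix list 17 of 18 values were above 0 with a median of 0.38, and 4 passed adjusted over the list alone, with lumican Lum at 0.95 ± 0.25 and decorin Dcn at 0.71 ± 0.14. The median of that list was 0.41 in ileum, 0.10 in control colon and 0.58 in DSS colon. The macrophage list had a median of 0.28 (0.48 in ileum, 0.18 in control colon and 0.12 in DSS colon) and 15 of 18 values above 0, and the cell cycle list a median of -0.20 and 1 of 24 values above 0, with 0 members adjusted over the list alone in both. Camera called 17 lists for genotype, 14 higher and 3 lower, and only some are described here. MHC class II was among the others, with a median of 0.52 in ileum and 0.49 in control colon but -0.10 in DSS colon. For the 4 lists above camera gave adjusted p values of 5.90e-14, 1.36e-14, 2.32e-09 and 3.02e-05 in that order. With an estimated correlation the adjusted p was 0.333 for the interferon list and 0.635 for the rest, and fry called none (smallest adjusted p = 0.294). Without either ileum array the interferon median was 0.23. Without the WT DSS array the cell cycle list was no longer called (median -0.04, adjusted p = 0.800), and without KO DSS replicate 1 its median was -0.09. With the smooth muscle mean as a covariate, added after seeing the data, it was -0.06 and no longer called (adjusted p = 0.122). Camera also called smooth muscle (median 0.36, 13 of 14 values above 0), endothelium (0.20, 11 of 12) and enteric neuron and glia (0.12, 13 of 14), each with 0 members adjusted over the list alone. Their adjusted p was 0.000829, 3.23e-05 and 0.0163, and 0.668, 0.635 and 0.672 with an estimated correlation. Without the WT DSS array smooth muscle and enteric neuron and glia took the other sign (-0.12 and -0.14) and were not called, and endothelium was at 0.12. Without KO DSS replicate 1 smooth muscle was at 0.12 and enteric neuron and glia at 0.02, the latter not called (adjusted p = 0.162). Without either ileum array the 3 medians were 0.61, 0.12 and 0.26, and without either control colon 0.56, 0.36 and 0.26. Across genes the KO minus WT difference in one condition barely tracked that in another (r = -0.04 for ileum and control colon, 0.04 for ileum and DSS colon, 0.04 for control and DSS colon). The call of Atg4b was lost, with values from -2.25 to -2.07, when any array other than KO DSS replicate 1 was left out (adjusted p from 0.0675 to 0.170), and also when all probe sets were tested (0.0560).

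Within DSS-treated colon, KO and WT (2 arrays against 1) gave 0 genes at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 776 of 19938, again fewer than that threshold would pass on average if no gene differed. Among the values that did not pass, the interferon-induced GTPase Gbp2b was at 4.05 ± 0.49 (KO minus WT, adjusted p = 0.464), Ifi44l at 3.67 ± 0.49 (adjusted p = 0.464) and the sperm protein gene Zan at 2.70 ± 0.22 (adjusted p = 0.149). Reg3g (2.72 ± 1.37) and Reg3b (2.53 ± 1.47) differed between the KO arrays themselves, with 4.62 and 4.59 in replicate 1 against 0.82 and 0.48 in replicate 2. Lowest among the genes that the naming rule ranks were Atg4b (-2.19 ± 0.18, adjusted p = 0.149), Hoxd13 (-1.70 ± 0.58), Fer1l4 (-1.69 ± 0.40), Wfdc18 (-1.69 ± 0.24) and St8sia5 (-1.66 ± 0.39). The noncoding AI506816, which the rule leaves out and which is named after its value was seen, stood at -4.08 ± 0.29 (adjusted p = 0.149). Values of the cytokine and chemokine list were above 0 for 9 of 28 genes with a median of -0.32, with Il1a at -1.41 ± 0.35, Ccl5 at -1.39 ± 0.19 and Ifng at -1.18 ± 0.16, and 4 of them passed adjusted over the list alone. All 24 cell cycle values were below 0 (median -0.42; -0.22 without KO DSS replicate 1 and -0.64 without replicate 2) and all 18 fibroblast matrix values above it (median 0.58), with 0 members adjusted over the list alone in both. All 14 smooth muscle values were above 0 with a median of 1.19 (0.56 without KO DSS replicate 1), again with 0 adjusted over the list alone. Camera called these 4 lists, and with an estimated correlation their adjusted p was 0.800, and fry called none (smallest adjusted p = 0.935). The count was 10 with a variance trend and robust fit. It also rose without either KO DSS array, but each such fit leaves 1 array per genotype in DSS colon, which is assumed to vary like the other groups. In simulation this comparison recovered 81.2% of genes changed by 2 log2 units and 1.49% of those changed by 1. In the measured data the deleted Atg4b itself did not pass at -2.19, nor did Zan, Gbp2b and AI506816 with larger differences. The count of 0 therefore does not argue against KO changes of 2 log2 units in DSS colon, whatever share the simulation recovered.

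Whether the KO effect differed between DSS colon and the controls was asked of the same arrays. No gene passed in limma (0 at an adjusted p under 0.05, smallest adjusted p = 0.571). The 639 of 19938 genes at an unadjusted p under 0.05 were fewer than that threshold would pass on average if no gene differed. In simulation 0% of genes changed by 2 log2 units were recovered, so differences of that size were not detectable here. Among the genes that the naming rule ranks, the widest values were those of the carbonic anhydrase Car3 (4.49 ± 1.84), Gbp2b (4.24 ± 0.63), Cyp2e1 (3.37 ± 1.25), the goblet cell protein Retnlb (3.34 ± 0.79) and Zan (3.04 ± 0.28) on the higher side. On the lower side stood St3gal4 (-2.49 ± 1.83), Ifi213 (-2.01 ± 0.67), Il1a (-1.95 ± 0.45), Wfdc17 (-1.95 ± 0.39) and Wfdc18 (-1.80 ± 0.32). The value of St3gal4 came from the ileum pair, with KO minus WT at 5.14 there, -0.47 in control colon and -0.16 in DSS colon. Outside the rule AI506816 stood at -3.81 ± 0.38, named after its value was seen. Car3 and Cyp2e1 were lower in KO than in WT control colon by -4.02 and -4.27, where 10 of 11 adipocyte genes were lower as well (median -1.38). Retnlb was lower in KO ileum (-1.79) and KO control colon (-2.52) and higher in KO DSS colon (1.18), each relative to WT. Without KO DSS replicate 2 the count was 279, and without KO DSS replicate 1 it was 18; each leaves a single array per genotype in DSS colon, which is assumed to vary like the other groups.

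**Figure D4:**
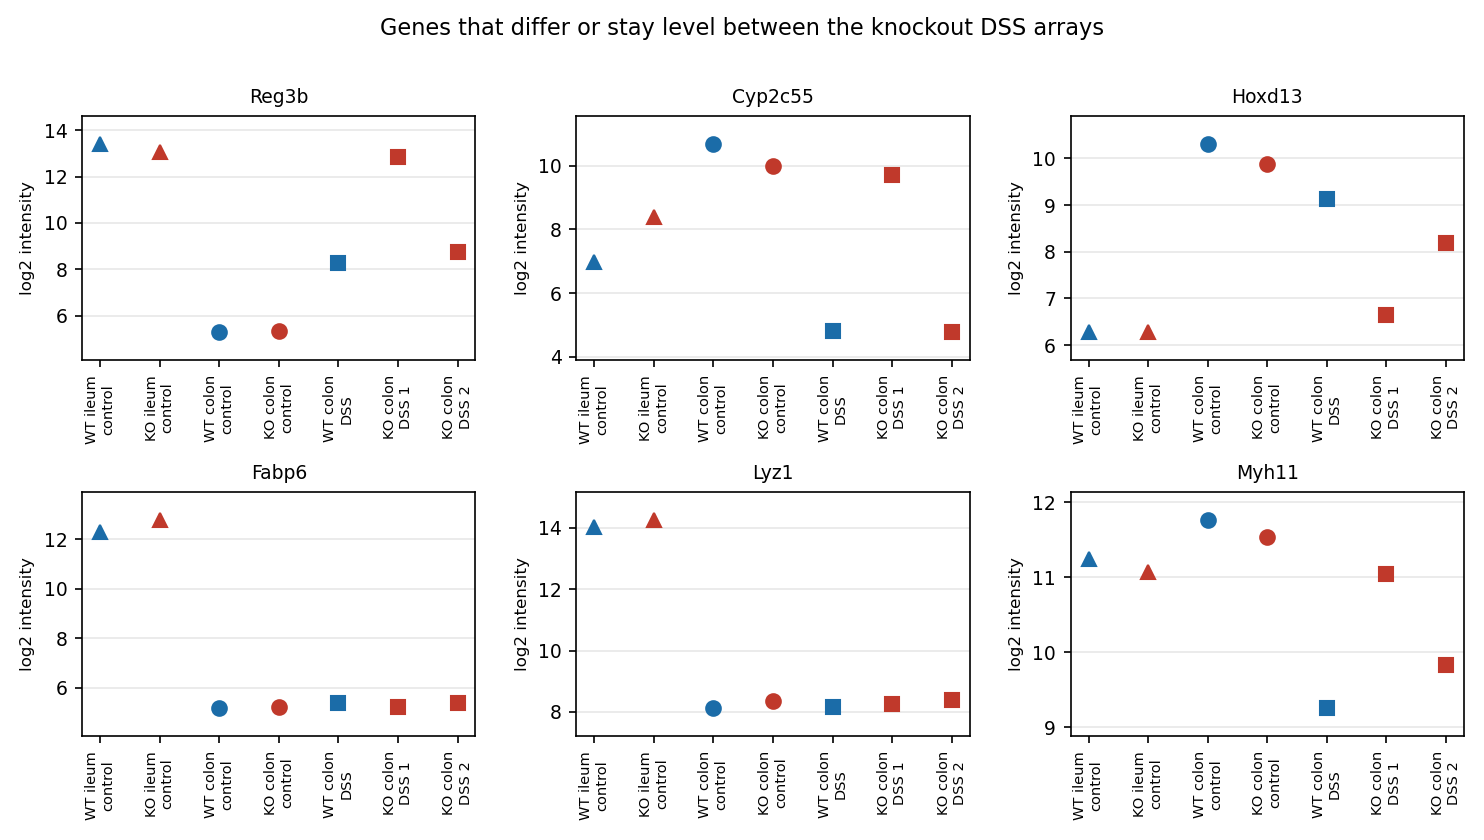
Log2 intensity (vertical axis) of Reg3b, Cyp2c55, Hoxd13, Fabp6, Lyz1 and Myh11 in each of the 7 arrays (horizontal axis), with colours and symbols as in the plot of Atg4b. Reg3b is at 12.85 in KO DSS replicate 1 and 8.74 in replicate 2, whereas Fabp6 and Lyz1 stay at the level of control colon in both.

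Single arrays of KO and WT ileum differed by more than 2-fold in 177 genes, 124 higher and 53 lower in KO. A difference between 2 arrays has no replicate check. Paneth cell genes stood out, with all 9 higher in the KO ileum by a median of 0.91 log2 units, above all 10000 random lists of matched expression (100th percentile). They included the angiogenin Ang4 (2.04), Habp2 (1.21), Pla2g2a (1.18) and Clps (1.17). The random lists hold unrelated genes, so for genes that vary together such a percentile does not test a KO effect. Between the 2 KO DSS arrays the smooth muscle list also lay at the 100th percentile (median 1.10). Among ranked genes the widest value was 5.14 for the sialyltransferase St3gal4, followed by Cyp3a11 (2.79), Mmrn1 (2.40), Rdh7 (2.40) and Fgf15 (2.37), the ileal hormone that represses bile acid synthesis. Lower in KO were the amino acid transporter Slc6a14 (-5.65), Saa1 (-3.43), Fa2h (-2.58), Tat (-2.55) and Slc40a1 (-2.50). The epithelial antimicrobial list had a median of -0.29, below all random lists, with Saa1 and the dual oxidase genes Duoxa2 (-2.23) and Duox2 (-1.77) lowest. Other lists lay at the 100th percentile too: complement (median 0.62, 8 of 10 higher), interferon (0.58, 18 of 21), MHC class II (0.52, 8 of 8), macrophage (0.48, 16 of 18), fibroblast matrix (0.41, 17 of 18) and enteroendocrine (0.31, 12 of 16). All 12 endothelial genes were higher (median 0.40) while all 10 tuft cell genes (-0.31) and 13 of 14 smooth muscle genes (-0.18) were lower.

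In control colon 92 genes differed by more than 2-fold between KO and WT, 35 higher and 57 lower. Adipocyte genes were lower in KO, 10 of 11 with a median of -1.38, below all random lists, with Retn at -2.51 and Lpl at -2.04. Cyp2e1 (-4.27), Car3 (-4.02), Adgrf1 (-2.74), the brown fat uncoupling protein Ucp1 (-2.53) and Retnlb (-2.52) had the lowest values of ranked genes, and Gdpd3 (2.11), Ifit1 (1.56), Greb1l (1.52), Map2 (1.41) and Kcnf1 (1.36) the highest. Of 35 autophagy genes 34 had values below 0 here, with a median of -0.27 at the 0.36th percentile of random lists. The matched random lists themselves lay below 0 in this pair, from -0.23 to -0.08 with the outer 2.5% on each side left out. The count below 0 therefore reflects in part a shift shared with other genes of like expression. Of the 35, 31 were below 0 with arrays centred on their medians and 27 under quantile normalization (medians -0.21 and -0.14). In ileum 24 of the 35 had values above 0 (median 0.06). Among the 5 colon arrays the WT control colon stood apart, with a list mean of 9.16 against 8.92 in KO control colon, 8.95 and 8.94 in KO DSS replicates 1 and 2 and 8.94 in WT DSS colon. The ileum means were 9.08 in WT and 9.16 in KO. WT DSS minus WT control colon gave -0.22 (25 of 35 lower), and KO minus WT in DSS colon -0.02. Between WT DSS and WT control colon 1413 genes differed by more than 2-fold, 701 higher and 712 lower. Ido1 (6.21), Clca4b (5.78), Cxcl9 (5.66), Nos2 (5.65) and Il1a (5.56) were highest, and Cyp2c55 (-5.87), Car3 (-5.04), Mptx1 (-4.60), Cyp2e1 (-4.60) and Nxpe2 (-4.24) lowest among ranked genes. All 11 adipocyte genes were lower in this pair, with a median of -1.38, below all random lists. The mean of that list was 8.04 in WT control colon and 6.41 in WT DSS colon, but 6.73 in KO control colon and 7.29 and 6.53 in KO DSS replicates 1 and 2.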

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

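Tests of explanations in this part were all chosen after the results were seen; the interaction test of the gene lists had been planned.

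In 3 arrays a sex marker appeared that the label rules out. The Y-linked Eif2s3y was at 9.39 in the WT ileum and 9.56 in the WT control colon, both labelled female, and Xist was at 12.16 in the WT DSS colon, labelled male. An exchange of the WT control colon and WT DSS arrays is argued against by the cytokine and chemokine list, whose median was 1.83 log2 units higher in the array labelled WT DSS. An exchange of WT and KO arrays is argued against by Atg4b, whose lowest WT value lay 1.90 log2 units above the highest KO value. A reversed sex entry for the WT animals may account for the pattern, since all 3 WT arrays carried the full pattern of the other sex and no KO array did. The origin of the mismatch stays open, and no biological explanation was tested.

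The DSS difference coincides with a sex difference in the markers, and 2120 genes differed. Of the called genes 1.84% lay on chromosomes X or Y, against 3.77% of the genes tested. With so few genes on X or Y, they could not have made up most of the calls. The share is therefore no test of sex-linked dosage as a cause. It shows only that a gene's own place on X or Y can bear on 39 of the called genes. Sex differences on the other chromosomes cannot be told apart from DSS for any of the 2081 other genes, because all DSS arrays were of one pattern and all control colons of the other; the treatment itself stays open in the same way. A smaller share of muscle in the DSS samples would raise goblet and colonocyte genes along with the interferon list, whose median was 2.71. The joint median of goblet and colonocyte genes was -0.10, but DSS also injures the epithelium, which could lower it, so it cannot decide. The interferon mean did not follow the smooth muscle mean over KO DSS replicates 1 and 2 and WT DSS colon (9.86, 9.92 and 9.69 against 10.55, 9.58 and 9.03). With the smooth muscle mean as a covariate the median of the interferon list was 2.11 and camera with the preset correlation still called it. Camera with an estimated correlation was not run with the covariate, and without it gave an adjusted p of 0.186.

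KO DSS replicate 1 stood apart. It differed from replicate 2 by more than 2-fold in 248 genes and from the WT DSS array in 514, whereas replicate 2 and the WT DSS array differed in 78. Ileal RNA in the sample is argued against, since the 33 genes higher in ileum than in control colon by 5 log2 units or more had a median difference of 0.17 between the replicates, with Fabp6 at -0.16 and Lyz1 at -0.11, although 8 of the 33 were 2-fold or more higher in replicate 1, such as Reg3b (4.11), Reg3g (3.81), Fabp2 (2.90), Alpi (2.62) and Slc13a1 (1.91). Sampling of another colon segment may contribute and stays open. Hoxb13 (-1.90) and Hoxd13 (-1.55) were lower, as were Casp14 (-2.96), Tgm3 (-1.79) and Insl5 (-1.41), while Cyp2c55 (4.92) and Cyp2c65 (4.38) were higher. The median over 8 Hox genes was -0.37, with 4 lower. Among them Hoxd12, at 5.83 and 5.62, lay below the lower quartile of all genes on both arrays and can show little change. The degree of injury was not tested. Hoxb13 lay farther from control colon in replicate 1 (8.59) than in replicate 2 (10.50), whereas the smooth muscle list lay nearer to it (10.55 against 9.58). Cyp2c55 also lay nearer to control colon (10.68 in WT) in replicate 1 (9.69). It was low in WT DSS colon (4.81) and replicate 2 (4.78), so its difference does not single out another segment. Cyp2c65 lay above WT control colon (7.26) in replicate 1 (9.72) and below it in replicate 2 (5.34). Genotype does not separate the pair, since both arrays are KO.

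Camera with the preset correlation found a different KO effect in DSS colon and in controls for 17 lists, none of which passed with an estimated correlation (smallest adjusted p = 0.701) or in fry (0.889). Positive medians were those of smooth muscle (1.34), adipocyte (1.21), enteric neuron and glia (0.81), goblet cell (0.72), tuft cell (0.41), fibroblast matrix (0.32) and fatty acid oxidation (0.17). Negative medians were those of MHC class II (-0.70), B and plasma cell (-0.66), cytokines and chemokines (-0.51), cell cycle (-0.40), neutrophil (-0.37), macrophage (-0.28), cholesterol synthesis (-0.27), interferon response (-0.26), complement (-0.24) and T and NK cell (-0.22). Most of these depended on single arrays. Without either ileum array macrophage (-0.01), T and NK cell (-0.09), complement (-0.01), cholesterol synthesis (-0.05) and tuft cell (0.21) were not called, and interferon was at -0.06, fibroblast matrix at 0.49 and fatty acid oxidation at 0.39. Without either control colon neutrophil (-0.24), fibroblast matrix (0.23) and fatty acid oxidation (0.07) were not called, and adipocyte was at 0.72, B and plasma cell at -0.44, complement at -0.49 and cholesterol synthesis at -0.51. Without KO DSS replicate 1 neutrophil (-0.21), complement (-0.26), cholesterol synthesis (-0.01) and tuft cell (0.17) were not called, and smooth muscle was at 0.75, cell cycle at -0.17, interferon at -0.17, T and NK cell at -0.35 and fibroblast matrix at 0.16. Without KO DSS replicate 2 fatty acid oxidation (0.18) was not called, and fibroblast matrix was at 0.52 and cholesterol synthesis at -0.55.

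KO minus WT medians of 3 lists had opposite signs in ileum and control colon, each beyond the outer 2.5% of random lists on its side, a difference that was not tested. Lists inside that limit in 1 of the 2 pairs are not counted, such as Paneth cell (0.91 and -0.25), crypt stem cell (0.28 and -0.24), immediate early (0.15 and -0.34) and fatty acid oxidation (0.12 and -0.34). They were -0.16 and 0.000688 for colonocyte markers, -0.12 and 0.0303 for cell cycle and -0.29 and 0.0160 for antimicrobial defence. In control colon 10 of 19 colonocyte values were above 0, their mean was -0.05 and quantile normalization gave a median of -0.02, so that sign is not firm.

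Probe sets without a single gene symbol were outside the comparisons. Of these 13723 probe sets 435 passed for DSS when all probe sets were tested, 332 higher and 103 lower.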

How the results depend on the processing

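The smooth muscle covariate and the removal of X and Y genes were chosen after seeing the data; the other settings were planned. The 20 genes named for DSS kept their sign in every setting that held them, and 17 to 20 passed where no single array was left out, except that the filter on dim genes removed 2, where all 18 others passed. The naming rule had already required the same direction in every array pair and a passed threshold, so the kept sign is no separate check. Without the WT or the KO control colon 11 and 12 of them passed. Of the 20 genes named for tissue 18 or more passed in every setting except that filter, which left out 6; all 14 others passed.

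Counts moved as follows. The genotype count of 1 became 0 with dim genes left out, which removes Atg4b itself, 0 with all probe sets tested (adjusted p of Atg4b 0.0560, more tests) and 0 in the 5 colon arrays (0.114, fewer arrays); leaving out single arrays gave 0 to 1. Over its alternatives the adjusted p of Atg4b ran from 0.00107 to 0.170. The DSS count of 2120 became 313 with the smooth muscle covariate and 183 to 3549 without single arrays. The tissue count of 1826 ranged from 660 to 2418 without single arrays. The KO against WT count in DSS colon of 0 became 1 with dim genes left out, the noncoding AI506816 (-4.08 ± 0.29, named after its value was seen), 10 with a variance trend and robust fit, and 0 to 538 without single arrays. The interaction count of 0 became 2 with a variance trend and robust fit (AI506816 and Zan) and 0 to 279 without single arrays. Apart from the settings that test more probes or fewer genes or arrays, the cause was not tested.

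Lists past the threshold fell to 0 with an estimated correlation in all 5 comparisons, and in fry to 9 for DSS, 8 for tissue and 0 for the other 3; the cause was not tested. Among lists past the threshold as reported, 4 reversed. For genotype, the Paneth cell list became -0.12 without either ileum array (-0.12 to 0.36 without single arrays), and without the WT DSS array smooth muscle became -0.12 (-0.12 to 0.61) and enteric neuron and glia -0.14 (-0.14 to 0.26). For DSS, the adipocyte list became 0.73 with the smooth muscle covariate and 0.29 without the WT control colon (-1.32 to 0.29). Lists not past it could change sign too: with that covariate the DSS medians of goblet cells (-0.13) and B and plasma cells (0.46) became 0.46 and -0.24, both called. The cause was not tested. The counts of genes over 2-fold between single arrays stayed within 1.5 times under both scalings. No paired analysis was possible because only KO DSS colon has numbered arrays. KO against WT in DSS colon and the interaction could not be fitted without the WT DSS array. Signal limits dim genes: Atg4b in KO arrays lay below the lower quartile, so its fold may be understated, as may those of genes below it on every array of their dimmer group, 2 of the 20 named for DSS and 11 of the 20 for tissue, and of Ido1 and Cyp2d12, below it on 1 array; the value of Atg4b over the alternatives ran from -2.25 to -2.07.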

Other observations

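Tests of explanations in this part were chosen after the results were seen.

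Clock genes differed between DSS and control colon. Cry1 (1.25 ± 0.12), Ciart (1.57 ± 0.32) and Per1 (0.99 ± 0.18) were higher and the repressor Nr1d1 (-1.23 ± 0.29) was lower, with 4 of 14 list members higher and 2 lower over all genes (4 and 4 adjusted over the list alone), and camera did not call the list. The labels used here give no time of day. Oxidative stress genes went both ways: the cystine transporter Slc7a11 (2.53 ± 0.20), heme oxygenase Hmox1 (1.63 ± 0.12) and Srxn1 (1.09 ± 0.10) rose while Gstm1 (-1.55 ± 0.27) fell, with 4 of 14 higher and 3 lower (4 and 5 adjusted over the list alone). The median of that list was -0.03 and its mean 0.15, and camera did not call it. Antibody genes fell in DSS colon, Ighm (-1.52 ± 0.16) and Jchain (-1.46 ± 0.16), in a B and plasma cell list in which 3 of 17 were lower and 0 higher, over all genes and adjusted over the list alone. The median of that list was nevertheless 0.46, and camera called it without the KO control colon (0.79, adjusted p = 0.0222) and, with the other sign, with the smooth muscle covariate (-0.24, adjusted p = 0.000237). Sprr1a, a cornified envelope gene of squamous epithelium, rose by 1.99 ± 0.23, the only member of 15 on its list to pass. The bile acid transporter subunit Slc51b rose by 2.53 ± 0.19, the only one of 24 small intestinal absorptive genes to pass.

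Several values in single arrays invite a second look. Gbp2b was at 10.91 and 10.77 in the KO DSS arrays but at 6.79 in the WT DSS array, close to its 7.00 in WT control colon, while 21 of 21 interferon list genes rose with DSS. Ifi44l showed the same split, at 10.03 and 8.95 against 5.82. Zan was at 6.34 in the WT DSS array and between 7.24 and 9.79 in the other 6. Ly6g, on the neutrophil list, was at 12.50 and 12.48 in the control colons and between 12.58 and 13.12 in DSS colon, against 5.11 and 4.95 in ileum, while the calprotectin genes S100a8 and S100a9 rose with DSS.

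A genotype effect could arise from the grouping of these arrays by chance. Of the 35 splits of the 7 arrays into 3 and 4, 34 could be fitted, the real one included. At least 1 gene passed in 10 of the 34; the real value was 1 and the highest of the others was 115. The real gene is the deleted Atg4b, at 7.35 to 7.72 in WT and 5.39 to 5.45 in KO arrays. Of the other 9 splits 4 part only the WT from the KO array of ileum or of control colon, so they hold a genotype difference themselves and are no measure of chance. The count of 115 came from parting KO DSS replicate 1 from the other DSS arrays, which points to a structure of the samples. The split by labelled sex gave 0, but the markers went against that label in 3 arrays, so this split does not test sex. For the interferon list 2 of the 34 splits gave a median as large as the real 0.34, with 0.58 as the highest of the others, which is the KO minus WT difference in ileum. The splits that keep 1 array of the smaller group in each condition number 12, too few for a share under 0.05; the highest of the others in these was 0 genes and an interferon median of 0.22. No conclusion on chance is drawn from the splits.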
